A study of Mus musculus with 6 samples.

How the data were processed

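The series holds 6 expression arrays of mouse regulatory T cells (Tregs), in 3 groups of 2. Per the labels, green fluorescent cells were sorted as CD4+CD25+FoxP3+ from spleen and lymph nodes of C57Bl/6 FoxP3-GFP reporter mice aged 8 to 11 weeks. Wild-type cells were incubated for 18 h with the DMSO vehicle (WT vehicle) or with 10 nM ATL1222, named in the labels as a selective agonist of the adenosine A2A receptor (WT ATL1222). Cells lacking that receptor were incubated with vehicle (KO vehicle). The labels call the replicates biological and do not say whether they came from separate animals, so p-values measure only the spread between these arrays. The gene of the receptor itself is not reported here, so the genotype labels carry no expression check.

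The deposited values are array signals, intensities on a linear scale for 45101 probe sets. Per the labels' protocols, biotin-labelled RNA was prepared from 1 µg of total RNA, and per the submitters' processing notes the authors processed the arrays with GCOS. The version and the summarization algorithm are not given in the sources used here. In the deposited values each array had the same mean after the highest and lowest 2% of probe sets were left out, and this scaling by the authors was kept. Median signals ran from 74.68 to 98.17 over the 6 arrays, and the ratio of 3' to 5' probe sets of Gapdh ran from 1.21 to 1.45 and that of Actb from 1.93 to 2.53. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.231. An exact test of 2 arrays against 2 cannot give a two-sided p below 0.33, so all tests of single genes borrow information across genes.

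In this work 64 control probe sets were left out. Of the rest, 34945 probe sets had 1 gene symbol in the platform's annotation, 932 had several and 9160 were not listed there. Symbols were updated through Entrez gene identifiers. For 34754 probe sets with 1 gene listed these matched a mouse gene table of assembly GRCm38.p6, used only for names and chromosomes. Probe sets with several symbols named no gene. Each of 18193 genes was represented by its probe set with the highest mean. Values were taken as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. The lowest 40% of genes by mean over all arrays were left out, a log2 mean below 6.45 or a signal of about 71.2, which left 10916 genes.

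Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 6 arrays in 1 fit, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison at a threshold of 0.05. The comparisons were KO vehicle against WT vehicle, WT ATL1222 against WT vehicle, and WT ATL1222 against KO vehicle, the last for counts and gene lists only. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists with at least 2 measured members, and again with an estimated correlation and with fry. Larger p-values with the estimate need not reflect correlation between genes. For the adenosine metabolism list in the knockout comparison the estimate was 0.00111, below the preset value. Its camera adjusted p still went from 0.147 to 0.590. Every list that passed in any comparison had an estimate above the preset value. These ran from 0.0346 for T cell receptor activation to 0.373 for co-inhibitory and co-stimulatory receptors. The p-values of those lists at the preset value may therefore be too small. The design, the alternatives, the rule for named genes and 21 gene lists with 394 different members were set before the data were examined. The lists covered Treg identity, co-inhibitory and co-stimulatory receptors, cAMP and CREB response, adenosine metabolism, T cell receptor activation, T helper factors, trafficking, proliferation, apoptosis, interferon response, glycolysis, stress, markers of other cell types, sex-linked genes and chromosomal neighbours of the receptor gene. Named genes were, for each comparison against WT vehicle, up to 10 higher and 10 lower genes with the largest fold change past the threshold and no overlap between groups. Where fewer than 10 passed in a direction, names were filled to 5 by smallest p and described as not passing. List members passing when adjusted over the list alone were named too (the 4 with the smallest p where over 6 passed), with 12 key genes whatever their values. The key genes Foxp3 and Gzmb were below the limit for dim genes and were not tested. Further genes named in a count, among them those of the third comparison, were chosen after their values were seen.

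Every group has a replicate 1 and a replicate 2. The spiked-in poly-A control RNAs, which are added before labelling, were brighter on replicate 1 in every group. The ratio of replicate 1 to replicate 2 lay between 1.41 and 2.19 for the Lys, Phe and Thr controls and was 1.16 in WT vehicle, 1.43 in KO vehicle and 1.06 in WT ATL1222 for Dap. The 3 hybridization controls, added after labelling, had ratios from 0.900 to 1.24, the highest for BioB in KO vehicle, and lay on both sides of 1. Deviations from the group means correlated between groups across genes at 0.230 for WT vehicle with KO vehicle, 0.230 for WT vehicle with WT ATL1222 and 0.147 for KO vehicle with WT ATL1222. The replicate number was therefore treated as a batch, called the labelling batch below, with 1 array of every group in each. The labels name no batch, and what set the replicate numbers apart was not tested. Values with the replicate number as a block are given where they change a named call or move a printed count by over 1.5 times.

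The fit was tested on simulated data in which 200 genes of 10916 were changed. Noise was drawn independently for each gene and array from the variances of the fit itself, without a batch. The rates below therefore hold only where that variance model does. For the knockout comparison, 58.7% of genes changed by 1 log2 unit and 90.6% of those changed by 2 units were recovered, with 7.20% false calls among all calls; for the agonist comparison these were 58.8%, 91.6% and 7.62%. Changes of 0.5 log2 units were recovered for 11.6% and 11.0% of genes. Alternatives were quantile and cyclic loess normalization, offsets of 1 and 64, no filter or a filter of 60%, the mean of a gene's probe sets, every probe set tested separately, variance models without trend or with robust estimation, fits on only the 4 arrays compared, the replicate block, and each array left out in turn. Added after seeing the data were a split of the control arrays for the correlation of fold changes and the order of the groups under both normalizations. Figures were drawn with matplotlib 3.10.9.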

Results

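Expression was measured on 6 arrays of sorted Tregs, CD4 T cells that restrain immune responses, after 18 h in culture. The groups were wild-type cells with vehicle, cells without the adenosine A2A receptor with vehicle, and wild-type cells with 10 nM of the receptor agonist ATL1222, with 2 arrays each. The A2A receptor is a G protein-coupled receptor that raises intracellular cAMP. All arrays held 45101 probe sets scaled to the same trimmed mean signal. Arrays of 1 group correlated across the genes tested with Pearson r between 0.958 and 0.967, and arrays of different groups with r between 0.953 and 0.971, so the groups did not separate by overall correlation.

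Several genes that mark Tregs were bright on every array. Ikzf2, the transcription factor Helios, had signals from 6810 to 8431, the surface receptor Nrp1 from 5319 to 8299, and the inhibitory receptor Ctla4 from 3432 to 6410. Others were dimmer: Il2ra, the CD25 gene used in the sort, had group means from 442.1 to 540.5, and Entpd1 from 168.7 to 227.1. The 1 probe set of Foxp3, the gene used to sort the cells, was listed at 7.18 to 53.5, below the limit for dim genes on all 6 arrays. Transcripts abundant in other immune cells stayed low: the highest signal on any array was 77.7 for the B cell gene Cd79a, 222.5 for the invariant chain gene Cd74, 123.3 for the myeloid gene Lyz2 and 249.1 for the CD8 T cell gene Cd8b1. The brightest markers of other cells were Ighm, the immunoglobulin mu heavy chain gene, at 4198 to 7539, and the cathepsin gene Ctss, at 4936 to 6457, followed by the adhesion gene Pecam1 at up to 475.9. The lists of B cell, myeloid, dendritic cell, CD8 T and NK cell, and stromal markers did not pass the list test in any comparison. They had 8, 3, 2, 6 and 4 measured members in that order, so the test says little for the shortest. The erythroid list had 1 measured member and was not tested. The list of naive CD4 T cell markers, cells that the sort for CD25 and FoxP3 would remove, was higher in the knockout than in WT vehicle (adjusted p = 0.0239, or adjusted p = 0.590 with an estimated correlation) and lower with ATL1222 than in the knockout (adjusted p = 0.00102, or adjusted p = 0.303 with an estimated correlation).

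The first comparison addressed what loss of the receptor changes in Tregs that received no agonist. 3 genes fell in the knockout and 0 rose. Rgs2, which speeds the shut-off of G protein signalling, was 2.52-fold lower, with a mean signal of 1439 ± 217 (SD, n = 2) in KO vehicle and 3653 ± 563 in WT vehicle (log2 fold change -1.33 ± 0.15 SE, limma adjusted p = 0.00484). Pdcd1, which encodes the inhibitory receptor PD-1, was 2.97-fold lower, at 984.0 ± 116 against 3039 ± 1044 (log2 -1.57 ± 0.19, limma adjusted p = 0.00484). Crem, a cAMP-responsive transcription factor gene, was 3.12-fold lower, at 514.4 ± 73.4 against 1683 ± 580 (log2 -1.64 ± 0.20, limma adjusted p = 0.00484). Within replicates 1 and 2 the log2 changes were -1.34 and -1.33 for Rgs2, -1.81 and -1.34 for Pdcd1, and -1.86 and -1.43 for Crem. Rgs2 and Pdcd1 lie on chromosome 1 and Crem on chromosome 18, whereas the receptor gene lies on chromosome 10. Among genes named below as lower in the knockout, Tnfaip3 and Gadd45b lie on chromosome 10 too. Whether they lie near the receptor gene was not examined.

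Genes next in order of p in the knockout did not pass. Odc1, the rate-limiting enzyme of polyamine synthesis, had a log2 fold change of -1.16 ± 0.20 (adjusted p = 0.158), and Tnfaip3, an inhibitor of NF-kB signalling, had -1.02 ± 0.21 (adjusted p = 0.547). Sil1, Zw10, Rps6ka5, Ppp1r3f and Tsc22d1 had the smallest p among genes with higher means, with log2 fold changes from 0.59 to 2.29 and adjusted p from 0.895 to 0.905. The Treg genes Ctla4, Icos, Nt5e, Entpd1 and Il2ra, the trafficking receptor Ccr7, the cytokine Il10 and the early response gene Nr4a1 had log2 fold changes between -0.71 and 0.03, each with adjusted p = 1.00. With the replicate number as a block, 9 genes passed, all of them lower, including the 3 above, Odc1 (adjusted p = 0.0102), Cebpb (adjusted p = 0.0102) and Tnfaip3 (adjusted p = 0.00180). Over all genes in the fit without the block, 425 had an unadjusted p under 0.05, where 546 would be expected by chance. The batch adds to the spread there, and no such number was taken with the block. The count was 0 without the variance trend, 0 with a gene's probe sets averaged and 0 with each probe set tested separately, and it was 7 without WT vehicle replicate 2 and 5 without KO vehicle replicate 2. Crem lay at log2 -0.85 with its probe sets averaged and had a second probe set at -1.09 ± 0.18, and Tnfaip3 a second one at 0.01 ± 0.36.

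Among the fixed lists, the cAMP and CREB response genes lay lower in the knockout. Of 26 measured members, 2 fell over all genes tested (Crem and Rgs2), 7 fell when adjusted over the list alone, and 20 had a negative log2 fold change, with a median of -0.31. The further 5 that fell over the list alone were Gadd45b (log2 -0.78 ± 0.16), Cebpb (-0.90 ± 0.20), Fosl2 (-0.83 ± 0.23), Dusp1 (-0.68 ± 0.21) and Bhlhe40 (-0.65 ± 0.20), the last 3 named after their values were seen. The list passed camera at adjusted p = 5.65e-11, with adjusted p = 0.445 with an estimated correlation. Of 18 genes of T cell receptor activation, 0 fell over all genes and 2 fell adjusted over the list alone, Tnfaip3 and the CD30 ligand gene Tnfsf8 (log2 -0.73 ± 0.19); the list was lower at adjusted p = 8.46e-06, and adjusted p = 0.445 with an estimated correlation. Of 8 T helper factors, 1 fell adjusted over the list alone, Bcl6 (log2 -0.53 ± 0.15), and the list was lower at adjusted p = 1.94e-04, or adjusted p = 0.549 with an estimated correlation.

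Of 14 co-inhibitory and co-stimulatory receptors, 1 fell in the knockout over all genes and adjusted over the list alone, Pdcd1, and the list was lower at adjusted p = 0.00610, or adjusted p = 0.618 with an estimated correlation. Of 26 Treg identity genes 0 passed singly on either adjustment, 18 had negative log2 fold changes, and the list was lower at adjusted p = 0.00355, or adjusted p = 0.618 with an estimated correlation. Of 10 naive CD4 T cell markers 0 passed singly and 8 had positive log2 fold changes; the list was higher at adjusted p = 0.0239, or adjusted p = 0.590 with an estimated correlation. The other 14 lists tested did not pass, with adjusted p from 0.0502 for glycolysis and hypoxia to 0.978 for proliferation and for sex-linked genes. With the replicate block the glycolysis list passed as well (adjusted p = 0.0157), lower in the knockout; without the block its adjusted p = 0.618 with an estimated correlation. The 24 measured neighbours of the receptor gene on chromosome 10 had a median log2 fold change of -0.01 (adjusted p = 0.874). Adjusted over the list alone with the block, 9 cAMP and CREB response genes, 4 of T cell receptor activation, 3 T helper factors, 2 Treg identity genes and 1 gene of adenosine metabolism fell. In that fit 1 naive CD4 T cell marker rose. Of co-inhibitory and co-stimulatory receptors 3 fell and 1 rose, and 3 trafficking genes rose and 2 fell. Without WT vehicle replicate 1, 2 lists passed in place of 6, and with no filter on dim genes 2 passed.

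**Figure D1:**
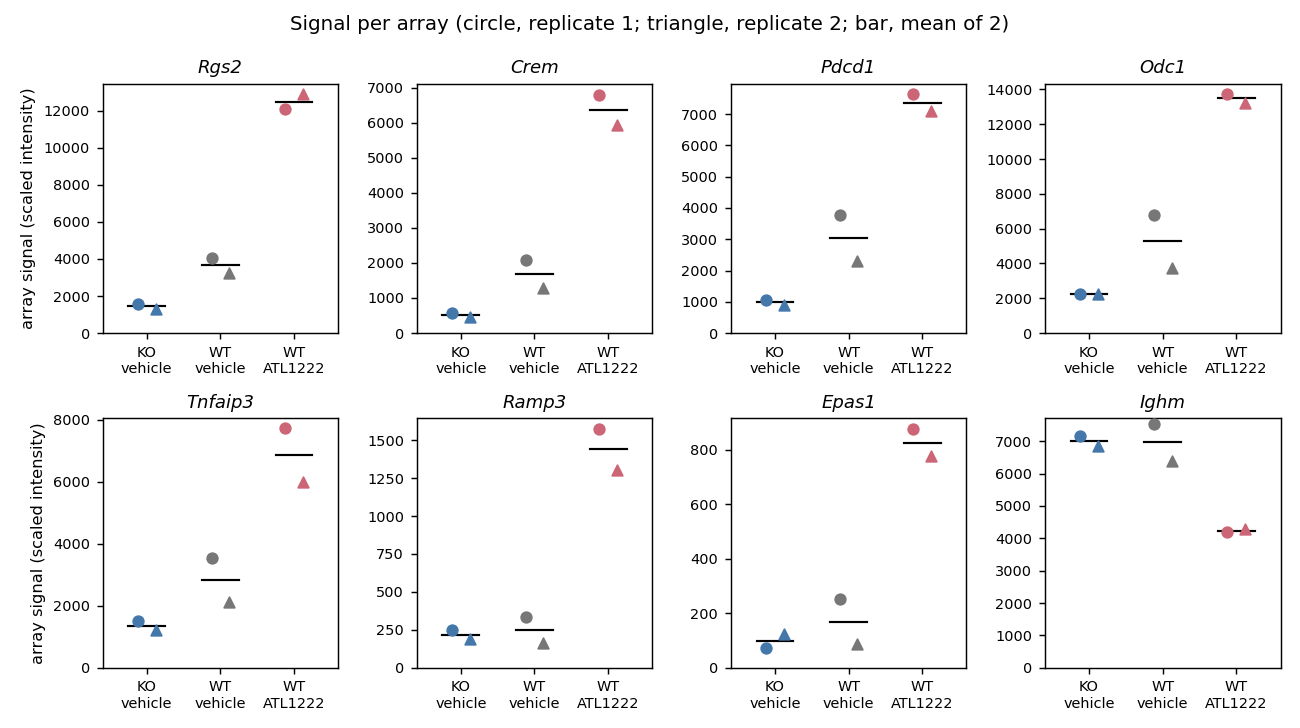
Array signal (scaled intensity, linear axis from 0) of 8 genes in KO vehicle, WT vehicle and WT ATL1222, with each array as a point and the mean of 2 arrays as a bar. Rgs2 lies at a mean of 1439 in KO vehicle, 3653 in WT vehicle and 12504 in WT ATL1222, while Ighm lies at 6967 in WT vehicle and 4237 in WT ATL1222.

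The second comparison addressed what the agonist changes in wild-type Tregs. With ATL1222, 22 genes rose and 1 fell. Rgs2 rose 3.43-fold, from 3653 ± 563 to 12504 ± 551 (SD, n = 2; log2 fold change 1.78 ± 0.15 SE, limma adjusted p = 1.51e-04), and Crem rose 3.86-fold, from 1683 ± 580 to 6361 ± 616 (log2 1.95 ± 0.20, limma adjusted p = 9.69e-04). The largest folds were those of Ramp3, which encodes an accessory protein of the calcitonin receptor-like receptor, at 5.75-fold (log2 2.53 ± 0.27, limma adjusted p = 9.81e-04), and of Epas1, which encodes the hypoxia-responsive transcription factor HIF-2 alpha, at 5.10-fold (log2 2.35 ± 0.38, limma adjusted p = 0.0180). Pdcd1 rose 2.49-fold, from 3039 ± 1044 to 7367 ± 388 (log2 1.32 ± 0.19, limma adjusted p = 0.00840). The 1 gene that fell was Ighm, by its brightest probe set, from 6967 ± 809 to 4237 ± 55.8 (log2 -0.71 ± 0.13, limma adjusted p = 0.0445). Its next brightest probe set gave log2 -0.24 ± 0.12. With a gene's probe sets averaged, Crem lay at log2 0.75 (adjusted p = 0.875), Fosl2 at 0.92 (adjusted p = 0.662) and Ighm at -0.06 (adjusted p = 0.999), and none of these 3 passed. With every probe set tested separately, a second one of Crem rose by log2 2.09 ± 0.18 (limma adjusted p = 0.00106). A second one of Fosl2 lay at 0.24 ± 0.48.

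The other genes that rose with the agonist included regulators of transcription, metabolism and signalling. The AP-1 member Fosl2 rose 3.03-fold, the ubiquitin ligase gene Rnf157 2.93-fold, the transcriptional inhibitor Id2 2.68-fold, Odc1 2.66-fold, the triglyceride synthesis enzyme Dgat1 2.59-fold and the co-stimulatory receptor Tnfrsf9 (4-1BB) 2.53-fold, with limma adjusted p from 0.00193 to 0.0322. Rgs1, a relative of Rgs2, rose 2.51-fold, Tnfaip3 2.47-fold and the transcriptional repressor Bcl6 1.89-fold (limma adjusted p = 0.0108, 0.0180 and 0.0199). Each of the genes named in this comparison as passing changed in the same direction within replicate 1 and within replicate 2, with log2 changes such as 1.58 and 1.98 for Rgs2, 1.01 and 1.62 for Pdcd1, and 1.74 and 2.96 for Epas1. For genes named by fold, the rule of no overlap between groups already forces the same direction, so this is no separate support. Among genes with lower means, the smallest p that did not pass were those of Id3 (log2 -0.80 ± 0.16, adjusted p = 0.0667), Cacna2d2 (-2.16 ± 0.43, adjusted p = 0.0674), Psg23 (-1.93 ± 0.40, adjusted p = 0.0809) and Rce1 (-0.93 ± 0.20, adjusted p = 0.0976). Ccr7 had a log2 fold change of 0.72 ± 0.14 and did not pass (adjusted p = 0.0534). Il10, Ctla4, Nt5e, Entpd1, Icos, Il2ra and Nr4a1 did not pass, with adjusted p from 0.631 for Nt5e to 0.998.

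With the replicate block 79 genes passed, 74 higher and 5 lower, and the 23 above were among them. The 5 lower genes were Ighm, Id3 (adjusted p = 0.00977), Cacna2d2 (adjusted p = 0.0223), Rce1 (adjusted p = 0.0223) and Psg23 (adjusted p = 0.0435). Cacna2d2 and Psg23 were dim with ATL1222, as given above. The higher genes also included Ccr7 (adjusted p = 0.00453), Stat3 (adjusted p = 0.00333), Tnfrsf18 (adjusted p = 0.00359), Tnfrsf4 (adjusted p = 0.00453) and Tnfsf8 (adjusted p = 0.0178). In the fit without the block, 549 genes had an unadjusted p under 0.05, where 546 would be expected by chance. The batch adds to the spread of that fit, and no such number was taken with the block. The count of 23 was 0 without the variance trend, 3 with probe sets averaged (Rgs2, Tnfaip3 and Ramp3), 9 with every probe set tested separately, 14 with no filter on dim genes, 35 after cyclic loess, 36 with a filter of 60% and 44 with only the 4 arrays compared. It was 5 without WT vehicle replicate 2, 5 without WT ATL1222 replicate 1, 39 without KO vehicle replicate 1 and 39 without KO vehicle replicate 2; Rgs2, Crem, Rnf157 and Ramp3 passed in each of these fits.

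The cAMP and CREB response list rose most clearly with the agonist. Of 26 measured members 6 rose over all genes tested (Crem, Rgs2, Fosl2, Rgs1, Gadd45a and Cebpb), 12 with the replicate block, 15 rose adjusted over the list alone, and 22 had positive log2 fold changes, with a median of 0.76. The list passed camera at adjusted p = 5.53e-24, with adjusted p = 0.313 with an estimated correlation. Of 8 T helper factors, 1 rose over all genes (Bcl6) and 5 adjusted over the list alone, the others being Stat3 (0.72 ± 0.15), Stat4 (0.44 ± 0.16), Maf (0.51 ± 0.21) and Il10 (1.36 ± 0.48). That list was higher at adjusted p = 2.00e-07, or adjusted p = 0.408 with an estimated correlation. Over all genes Stat3, Stat4, Maf and Il10 did not pass (limma adjusted p = 0.0809, 0.735, 0.873 and 0.719). The mean Il10 signal in WT vehicle was 84.77 ± 39.8, near the limit for dim genes.

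Of 14 co-inhibitory and co-stimulatory receptors, 2 rose with the agonist over all genes (Pdcd1 and Tnfrsf9) and 5 adjusted over the list alone, with Ctla4 (log2 0.47 ± 0.16), the OX40 gene Tnfrsf4 (0.67 ± 0.18) and the GITR gene Tnfrsf18 (0.65 ± 0.17); the list was higher at adjusted p = 9.39e-06, or adjusted p = 0.560 with an estimated correlation. Of 26 Treg identity genes 1 rose over all genes (Tnfrsf9) and 4 adjusted over the list alone, with Tnfrsf18, Tnfrsf4 and the adenosine-producing enzyme gene Nt5e (0.42 ± 0.14); the list was higher at adjusted p = 0.00344, or adjusted p = 0.560 with an estimated correlation. Tnfrsf4, Tnfrsf9 and Tnfrsf18 are members of both lists. The T cell receptor activation list did not pass (adjusted p = 0.236): 2 members rose over all genes (Tnfaip3 and Tnfrsf9), and adjusted over the list alone 3 rose, with Tnfsf8 (0.94 ± 0.19), and Nfatc2 fell (-0.68 ± 0.20). The median of that list, -0.09, had the opposite sign to its test. Over all genes Nfatc2 did not pass (limma adjusted p = 0.473). Its log2 change ran from -0.866 to -0.089 over the alternatives. In the knockout Nfatc2 also lay below WT vehicle, at -0.595 ± 0.202. In adenosine metabolism, where the list did not pass (adjusted p = 0.358), Nt5e and the adenosine kinase gene Adk (0.38 ± 0.13) rose adjusted over the list alone. The naive CD4 T cell list did not pass (adjusted p = 0.138), with Ccr7 higher and Id3 lower adjusted over the list alone. The remaining lists did not pass, with adjusted p from 0.0888 for glycolysis and hypoxia to 0.921 for the trafficking, dendritic cell and stromal lists. With the replicate block, 3 Treg identity genes, 4 co-inhibitory and co-stimulatory receptors, 2 T helper factors and 1 trafficking gene rose over all genes. Adjusted over the list alone in that fit, 7 Treg identity genes rose and 1 fell, 2 trafficking genes rose and 3 fell, and 2 glycolysis genes rose. Without WT ATL1222 replicate 2, 8 lists passed in place of 4.

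**Figure D2:**
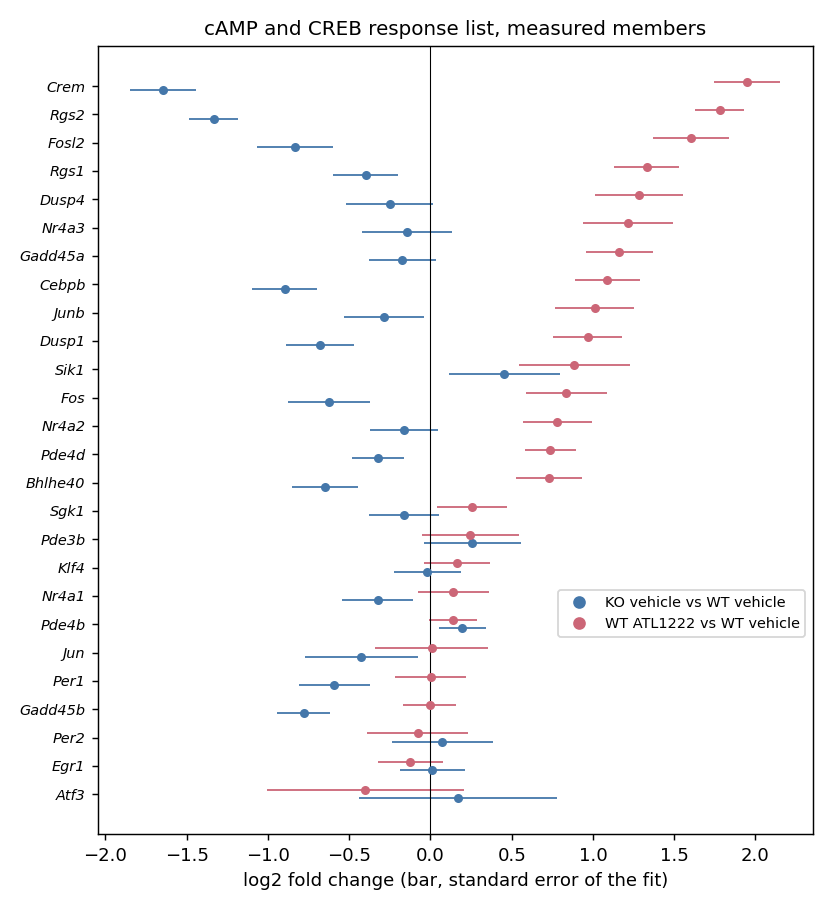
Log2 fold changes of the 26 measured members of the cAMP and CREB response list against WT vehicle, as points with the standard error of the fit as bars, in KO vehicle and in WT ATL1222 (n = 2 arrays per group). In the knockout 20 members lie below 0, and with ATL1222 22 lie above 0, with Crem at -1.64 and 1.95.

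Set side by side, the 3 genes that fell in the knockout were among the 22 that rose with the agonist, where 0.0060 would be expected if the lists were independent. Of those 22 genes, 21 had lower means in the knockout than in WT vehicle, with a median log2 fold change of -0.56, and 14 of them had an unadjusted p under 0.05 there. The exception was the splicing factor gene Isy1, named after its value was seen, at 0.01. Within replicate 1, 22 of the 22 genes were lower in the knockout, within replicate 2, 19, and within both, 19. Over all 10916 genes the log2 fold changes of both comparisons correlated with Pearson r = 0.302 across genes, which are not independent replicates. The comparisons share the WT vehicle arrays, and 100 simulations of unchanged groups against shared controls gave a mean r of 0.501 (0.472 to 0.522). The covariance was 0.0288 against 0.0429 in the simulations, a difference of -0.0141, and 59.8% of genes had the same sign against 66.7%. All 3 values thus lay below those of unchanged groups simulated without a batch. A batch shared between groups cancels in each comparison, so the simulated covariance may be too high. Part of the difference in covariance may therefore come from the simulation. With 1 control array shared, r was 0.588 without WT vehicle replicate 1 and 0.550 without WT vehicle replicate 2, against a simulated mean of 0.667 for each. With a filter of 60% on dim genes r was 0.099 against 0.501. With no array shared, the knockout change taken within 1 replicate number and the agonist change within the other, r was -0.104 and -0.038, with covariances of -0.0192 and -0.0064. This split was chosen after seeing the data.

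**Figure D3:**
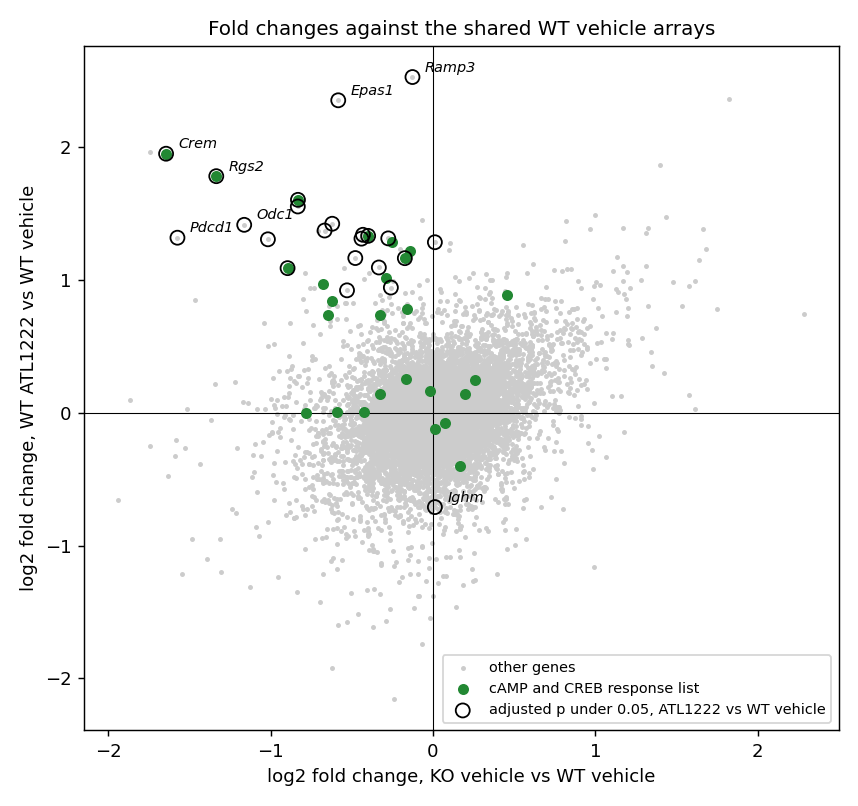
Log2 fold change of WT ATL1222 (vertical) against that of KO vehicle (horizontal), each relative to WT vehicle, for 10916 genes (grey), with the cAMP and CREB response list in green and the 23 genes past the threshold with ATL1222 circled. Of the 22 circled genes that rose, 21 lie left of 0, among them Crem, Rgs2 and Pdcd1 at -1.64, -1.33 and -1.57.

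The third comparison set the agonist-treated wild-type cells against the knockout cells. These groups differed in both genotype and treatment, and no knockout cells received the agonist, so their effects cannot be told apart. Members said to rise or fall here were higher or lower with ATL1222 than in the knockout. All 6 arrays set the variance, and the WT vehicle arrays took no part in the means compared. Here 109 genes passed, 96 higher and 13 lower with ATL1222 (140 with only the 4 arrays compared), and 926 had an unadjusted p under 0.05. Of the cAMP and CREB response list 14 of 26 members rose over all genes and 16 adjusted over the list alone, with the largest changes in Crem (log2 3.59 ± 0.20) and Rgs2 (3.11 ± 0.15); the list was higher at adjusted p = 4.29e-30, or adjusted p = 0.227 with an estimated correlation. Of 14 co-inhibitory and co-stimulatory receptors 5 rose over all genes (Pdcd1, Ctla4, Tnfrsf4, Tnfrsf9 and Tnfrsf18), and adjusted over the list alone 6 rose and 1 fell (adjusted p = 8.49e-07, or adjusted p = 0.303 with an estimated correlation). Of 8 T helper factors 3 rose over all genes (Bcl6, Stat3 and Maf) and 6 adjusted over the list alone (adjusted p = 1.22e-10, or adjusted p = 0.233 with an estimated correlation). Of 26 Treg identity genes 4 rose over all genes, and adjusted over the list alone 8 rose and 1 fell (adjusted p = 4.65e-06, or adjusted p = 0.303 with an estimated correlation).

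T cell receptor activation genes were also higher with ATL1222 than in the knockout, with 3 of 18 members rising over all genes and 6 adjusted over the list alone (adjusted p = 7.54e-05, or adjusted p = 0.233 with an estimated correlation). The glycolysis and hypoxia list was higher with 1 of 17 members rising on either adjustment, Hif1a (log2 0.72 ± 0.14; adjusted p = 0.00110, or adjusted p = 0.303 with an estimated correlation). The stress list was higher with 1 of 16 members rising on either adjustment, Xbp1 (0.75 ± 0.14; adjusted p = 0.0279, or adjusted p = 0.666 with an estimated correlation). Naive CD4 T cell markers were lower: of 10 members 1 rose (Ccr7) and 1 fell (Id3) over all genes, while adjusted over the list alone 1 rose and 4 fell (adjusted p = 0.00102, or adjusted p = 0.303 with an estimated correlation). The other 12 lists tested did not pass, with adjusted p from 0.0548 for adenosine metabolism to 0.935 for B cell markers. The count of 109 was 264 with the replicate block (205 higher, 59 lower), 5 without the variance trend, 44 with probe sets averaged, 70 with no filter, 61 without KO vehicle replicate 2 and 42 without WT ATL1222 replicate 1. With the block, 9 Treg identity genes rose and 1 fell over all genes, and 6 T helper factors rose. Likewise 3 trafficking genes rose and 3 fell, 1 naive CD4 T cell marker rose and 3 fell, and 2 glycolysis genes rose. Adjusted over the list alone with the block, 8 glycolysis genes rose and 1 fell, and 2 stress genes rose. Only the cAMP and CREB list passed fry (adjusted p = 0.0476).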

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

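Of the tests of explanations in this part, only that of the array scaling was chosen before its result was seen; the others were chosen after. The fit on separate probe sets was planned.

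Probe sets without a single gene name took no part in the comparisons of genes. Among 5839 of them that were bright enough, 10 passed in WT ATL1222 against KO vehicle, 9 higher and 1 lower, when every probe set was tested separately in limma; 0 passed in each comparison against WT vehicle, where the same fit called 0 named probe sets in the knockout and 9 with ATL1222. It called 78 named ones in WT ATL1222 against KO vehicle.

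Genes raised by the agonist in wild-type Tregs lay lower in the knockout, 21 of 22 of them, with a median log2 fold change of -0.556. Noise in the shared WT vehicle arrays moves both comparisons the same way, so it forbids this opposite sign; in 100 simulations of unchanged groups the corresponding median lay between 0.229 and 0.694. The scaling of the arrays is argued against as well. After quantile normalization or cyclic loess, whichever gave the smaller count, 21 of the 22 genes were lower. Each replicate number, treated here as a labelling batch, held 1 array of every group. A shift common to the arrays of 1 number cancels in each comparison and cannot give the pattern. The 19 genes lower within both replicate numbers are therefore no separate test of the batch. Receptor signalling in the wild-type cultures without added agonist stays open as a hypothesis: 19 of 26 members of the cAMP and CREB response list had group means in the order knockout, vehicle, agonist, but the 20 members below 0 in the knockout and the 22 above 0 with the agonist already force at least 16, so this count is no separate test. A difference between the mice that supplied each genotype may also account for part of it and was not tested, because the labels give no litter or cage.

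Ighm was lower with ATL1222, by log2 0.71. Fewer B cells among the sorted cells, which the sort for CD4 would remove, stays undecided as the whole cause. Of 7 transcripts abundant in B cells 3 were tested, Cd74, Cd79b and Ms4a1. Their changes had a median of 0.197 and lay above that of Ighm by 0.74 ± 0.33, 0.91 ± 0.28 and 1.00 ± 0.32 log2 units (SE). Their signals ran from 128.8 to 222.5, 186.8 to 258.7 and 150.0 to 242.5. Those of Ighm ran from 4198 to 7539, and the limit for dim genes was 71.2. Part of such low signals may be background, which could not fall with fewer B cells, so these 3 cannot decide. The other 4 were too dim to test, with signals of at most 126.8 for H2-Aa, 102.9 for H2-Eb1, 77.7 for Cd79a and 74.5 for H2-Ab1. A change in only part of the transcripts that carry the gene may be involved, since the next brightest probe set changed by 0.468 log2 units less (standard error 0.175). Both probe sets lie on the same arrays, and no second platform was used here.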

How the results depend on the processing

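All alternatives here were planned except the split of the control arrays, chosen after seeing the data; none could be run for the receptor gene. The 3 genes of the knockout comparison passed in each alternative except 3, with counts of 0 when probe sets were averaged, 0 when each was tested separately and 0 without the variance trend; the count was 9 with the replicate block and 3 to 7 with 1 array left out. The agonist count of 23 became 35 with cyclic loess, 14 with no filter, 36 with the 60% filter, 3 with probe sets averaged, 9 with every probe set separately, 0 without trend, 44 with only the 4 arrays compared, 79 with the replicate block, and 5 to 39 with 1 array left out. Agonist against knockout, 109, became 70 with no filter, 44 with probe sets averaged, 5 without trend, 264 with the replicate block, and 42 to 133 with 1 array left out. The correlation of fold changes, 0.302, was 0.099 with the 60% filter and 0.214 to 0.588 with 1 array left out, lay between 0.252 and 0.459 with the other planned settings, and was -0.104 and -0.038 with no array shared, which removes the part that the controls add. Filters change how many genes are tested, 18193 or 7277 in place of 10916, and separate probe sets 27022; the cause of the other shifts was not tested. Lists passing for the knockout, 6, were 2 with no filter, 0 with an estimated correlation, 0 with fry and 2 to 7 with 1 array left out; for the agonist, 4, they were 0 with an estimated correlation, 0 with fry and 3 to 8 with 1 array left out; and for agonist against knockout, 8, they were 0, 1 and 6 to 8 in that order. Of 306 alternative values of lists that passed, 253 kept direction and side of the threshold, 53 lost the call and 0 reversed; calls gained by other lists are not in this tally. Of 960 alternative values of named genes, 842 stayed on their side, 70 lost the call, 36 gained it and 12 changed sign, all in genes that did not pass: in the knockout with probe sets averaged, Zw10 at -0.073, Entpd1 at 0.039 and Nt5e at 0.143; with 1 array left out, Nr4a1 (-0.654 to 0.007), Icos (-0.389 to 0.014), Ccr7 (-0.187 to 0.030) and Il2ra (-0.160 to 0.219) in the knockout, and Nr4a1 (-0.051 to 0.330) and Icos (-0.209 to 0.274) with the agonist. A group left with 1 array was assumed to vary like the others. The replicate block kept all 3, 23 and 109 calls and added others; it is the paired form of the fit. Genes whose mean over all arrays lay below about 71.2 were not tested, which leaves Foxp3, Gzmb and 7277 genes in all without a result.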

Other observations

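The genes and groups in this part were chosen after their values were seen. WT ATL1222 against KO vehicle held further genes past the limma threshold. The glucocorticoid receptor gene Nr3c1 was higher by log2 1.24 ± 0.15 (adjusted p = 6.03e-04), the insulin receptor substrate Irs2 by 1.69 ± 0.23 (adjusted p = 0.00121), the opioid precursor gene Penk by 1.54 ± 0.28 (adjusted p = 0.0150), and the interleukin-2 signal transducers Stat5a and Stat5b by 0.74 ± 0.16 and 0.68 ± 0.15 (adjusted p = 0.0392 and 0.0387). The largest change outside the lists was in the methionine sulfoxide reductase gene Msrb3, at 3.70 ± 0.40 (adjusted p = 2.07e-04). Of integrin genes, Itga4 (from the trafficking list; -0.81 ± 0.15, adjusted p = 0.0178) and Itga6 (-0.65 ± 0.13, adjusted p = 0.0297) were lower and Itgav (0.94 ± 0.18, adjusted p = 0.0213) was higher. In the knockout against WT vehicle none of these 9 genes passed; Msrb3 had log2 -1.74 with adjusted p = 0.704.

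Genes whose arrays separated all 3 groups without overlap fell unevenly into the 6 possible orders. The order knockout, vehicle, agonist from lowest to highest held 213 genes and the opposite order 201, while the other 4 orders held 75 to 106. Chance gives 121 in each if all arrays are interchangeable, which leaves out the labelling batch; with the group labels of replicate 2 reassigned in the 5 other ways, which mixes the groups, an order held 48 to 155 genes. The 2 fullest orders held 251 and 223 genes after quantile normalization and 271 and 208 after cyclic loess. Of the 213 genes, 57 differed by over 2-fold between the outer groups, and of the 201 genes, 12. In a scan of 164 gene families named by symbol, the dual-specificity phosphatases (Dusp, 16 measured members) were lower in the knockout, with 15 negative log2 fold changes, 16 after quantile normalization and 15 after cyclic loess, and a median of -0.225, although 0 members passed singly; Dusp1 and Dusp4 are also members of the cAMP and CREB response list. Camera gave this family adjusted p = 0.00117 over the scan, and adjusted p = 0.989 with an estimated correlation. With the agonist against WT vehicle 9 of the 16 members were negative, with a median of -0.042, and against the knockout the family was higher (adjusted p = 0.0117, or adjusted p = 1.00 with an estimated correlation), with Dusp1, Dusp4 and Dusp10 past the threshold. The only other family past the threshold in the scan was that of the tumour necrosis factor receptors (Tnfrsf, 9 measured members), higher with the agonist than in the knockout. Its adjusted p = 0.0415, or adjusted p = 1.00 with an estimated correlation, its median was 0.200, and 5 members were positive, as after quantile normalization and cyclic loess. Of these Tnfrsf4, Tnfrsf9 and Tnfrsf18 passed singly, and all 3 are also in the fixed receptor list.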
